A study of Saccharomyces cerevisiae with 29 samples.

How the data were processed

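The labels describe 29 samples of W303 budding yeast (MATa, RAD5): 17 total RNA libraries, 10 chromatin immunoprecipitation or input samples and 2 Micro-C samples. The 17 RNA libraries were used, and the other 12 samples were not analysed here. Per the labels, cultures in rich medium with 2% glucose were arrested in G1 with 5 µg/ml α-factor for 170 min at 25 °C, or exposed in S phase to 0.033% MMS for 60 min. RNA was taken by hot phenol and sequenced as rRNA-depleted, strand-specific libraries. The labels add that the rad50Δ and rrp6Δ strains carry a thymidine kinase cassette at URA3, and that the deletions used KAN (rad50), HIS (mre11, ku70), TRP (rrp6) and ADE2 (xrn1) markers.

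Per the submitters' processing notes, the authors aligned reads with STAR 2.5.3 to build R64, and used SAMtools 0.1.19 and DESeq2 (no version stated). The deposited signal values are read counts per annotated row divided by 1 size factor per library. All of the values of every library (100%) lay within 0.02 of a whole multiple of a single step, so whole reads could be taken back in 16 of 17 libraries. In the ku70Δ library the step lay within 1 percent of 1, and its reads were not taken back. The deposited signal densities (25 columns, count per base of the row, by the authors) and 8 columns of group means were not used. Which program counted the reads, and how it treated reads with several alignments, is not stated. Rows overlap: each coding gene has an ORF row and a transcript row, and XUT, SUT and CUT rows overlap each other. Strand was checked on 37 dubious ORFs that lie inside a coding gene of the other strand, whose values per base were a median of 0.344% of those of the gene.

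The file holds 20318 rows: 5798 coding, 809 dubious, 5798 transcript, 3922 divergent, 1798 XUT, 925 CUT, 847 SUT, 299 tRNA, 77 snoRNA, 24 rRNA, 15 ncRNA and 6 snRNA rows. Of the divergent rows, 62.5% are windows of 591 bp. Rows with a mean of at least 10 over all libraries (16559, of which 5580 coding) were tested. Depth over ORF rows ran from 7512010 reads (first mre11Δ library) to 32942688 (first H125N library). It was 15676253, 11222979, 23108688 and 20332700 in wild type, 9755405 and 13768693 in rad50Δ, 9003630 in the other mre11Δ library, and 8322153 and 11984743 in MMS. The 10 highest genes held 7.98% to 13.3% of the coding total. Replicate pairs correlated at r = 0.961 to 0.997 on the log scale, and their spread was 13.2 to 166 times that of counting alone (chi-square over its degrees of freedom), so spread between libraries, not counting, set the precision.

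Libraries were grouped by genotype and treatment, and comparisons were fixed before the data were examined. Values plus 1 were taken to log2 and fitted with limma 3.58.1 (R 4.3.3), with empirical Bayes moderation using a trend and robust settings, over 17 libraries in 8 groups (9 residual degrees of freedom). P values were adjusted by the Benjamini-Hochberg method over the 16559 rows, with a threshold of 0.05. The 1 ku70Δ library has no spread of its own and was assumed to vary like the other groups. Comparisons were each mutant or MMS against wild type in G1, the average of rad50Δ and mre11Δ against wild type, mre11Δ against mre11-H125N, rad50Δ against mre11Δ, and the average of the deletions minus mre11-H125N.

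Gene lists were written from general knowledge of yeast: MRX and end joining, DNA damage response, stress-induced, ribosomal protein, ribosome biogenesis, pheromone response, G1/S, histone, G2/M, M/G1 daughter-cell, glycolytic, phosphate, adenine and one-carbon, galactose, Gcn4 target, sulfur and methionine, iron, RNA decay, Mediator, nuclear pore, subtelomeric family, within 20 kb of an end, α-cell marker, mating cassette, meiosis and sporulation, mitochondrially encoded, nitrogen catabolite and autophagy, and cell wall integrity genes. The list of genes within 20 kb of an end was corrected after the values were seen, to leave out the mitochondrial genome. Lists and RNA classes were tested with camera, with a preset correlation of 0.01 and with an estimated correlation. The 3 α-cell markers and 2 mating cassettes were too few for it.

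Named genes followed a rule. They were the 10 higher and 10 lower coding genes with the largest change among those past the threshold whose libraries all lay beyond all wild-type libraries. From each list with a call, 2 per direction with the smallest adjusted p were added, and from each RNA class the 3 with the smallest p. The text names a part of them. Deleted genes and marker genes stand outside the rule.

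Alternatives were pseudocounts of 0.5 and 8, no filter or a mean of 50, TMM factors or median-of-ratios factors from coding genes, edgeR 4.0.16 and DESeq2 1.42.0 on the whole reads, fits with only the groups compared, the replicate number as a block, an added minimum of 1 log2, and leaving out each library. Chosen after the data were seen were wild type 1 and 2 only, wild type 3 and 4 only, no number 1 library of wild type, rad50Δ or mre11Δ, a block over 6 libraries, the same 6 without the block, thinning to the shallowest library, and transcript rows in place of ORF rows. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

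The fit was tested on simulated data with known changes of 0.5, 1 and 2 log2 drawn around the real levels of all coding genes fitted together. It recovered 8.96%, 71.6% and 95.4% of them with the libraries of mre11Δ (5543 genes in the fit), 16.4%, 76.1% and 95.4% with those of mre11-H125N (5544), and 4.48%, 44.8% and 95.5% with that of ku70Δ (5545). The false share of calls was 7.20%, 4.62% and 6.80%. The list test gave an unadjusted camera value of 1.19e-34 for a shifted simulated list and 0.298 for an unshifted one. Simulated genes were drawn independently, without deviations shared between genes or libraries. The simulation therefore cannot show the false share or the list test under such shared deviations. Only 65 to 67 genes were changed at each size, in a single group, and p values were adjusted over coding genes alone. The real comparisons had other shares of changed genes and were adjusted over 16559 rows, so the recovered shares may not hold for them.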

Results

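Total RNA was profiled in W303 budding yeast held in G1 with α-factor. There were 4 wild-type libraries and 2 each of rad50Δ, mre11Δ, mre11-H125N, rrp6Δ and xrn1Δ, with 1 of ku70Δ and 2 of wild type in S phase with methyl methanesulfonate (MMS). Mre11 and Rad50 form, with Xrs2, the MRX complex of DNA end processing, and H125N replaces a residue of the Mre11 nuclease site. Rrp6 is a nuclease of the nuclear exosome, Xrn1 the main cytoplasmic 5′ to 3′ exonuclease and Yku70 a subunit of the Ku complex that binds DNA ends. Each change is a ratio of group means and a log2 change with its standard error, against the 4 wild-type G1 libraries unless stated. "Rose" and "fell" mean an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. For gene lists and RNA classes, the first adjusted p is that of camera with a preset correlation of 0.01 between genes, and the other is marked. Nothing in the labels says that replicates were separate cultures, so the p values measure only the spread between these samples. Unless stated, every library of the mutant lay beyond all 4 wild-type libraries for each gene named. Of the genes picked by rule, 47 of 77 in rad50Δ, 50 of 80 in mre11Δ, 25 of 29 in mre11-H125N, 33 of 75 in rrp6Δ, 8 of 102 in xrn1Δ, 11 of 25 in ku70Δ and 21 of 102 in MMS lost their call in at least 1 alternative analysis.

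The transcript of each deleted gene was absent or nearly absent in its mutant. RAD50 (YNL250W, chromosome 14, 175410 to 179348, build R64) stood at 0 and 2.58 normalized reads in the rad50Δ libraries against 1034 ± 132 (mean ± SD) in wild type. MRE11 (YMR224C, chromosome 13, 718575 to 720653) had 0 reads in mre11Δ, against 659.6 ± 40.0 in wild type, and kept 669 ± 14.8 in mre11-H125N. RRP6 (YOR001W, chromosome 15, 326832 to 329033) stood at 1.73 and 1.05 in rrp6Δ, against 3459 ± 256. XRN1 (YGL173C, chromosome 7, 175527 to 180113) stood at 9.84 and 15.8 in xrn1Δ, against 11149 ± 655. YKU70 (YMR284W, chromosome 13, 838187 to 839995) stood at 2.99 in ku70Δ, against 686 ± 138 in wild type, in a library assumed to vary like the other groups. XRS2 did not change in either MRX deletion (rad50Δ log2 0.06 ± 0.12, adjusted p = 0.786, mre11Δ log2 0.04 ± 0.12, adjusted p = 0.851).

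**Figure D1:**
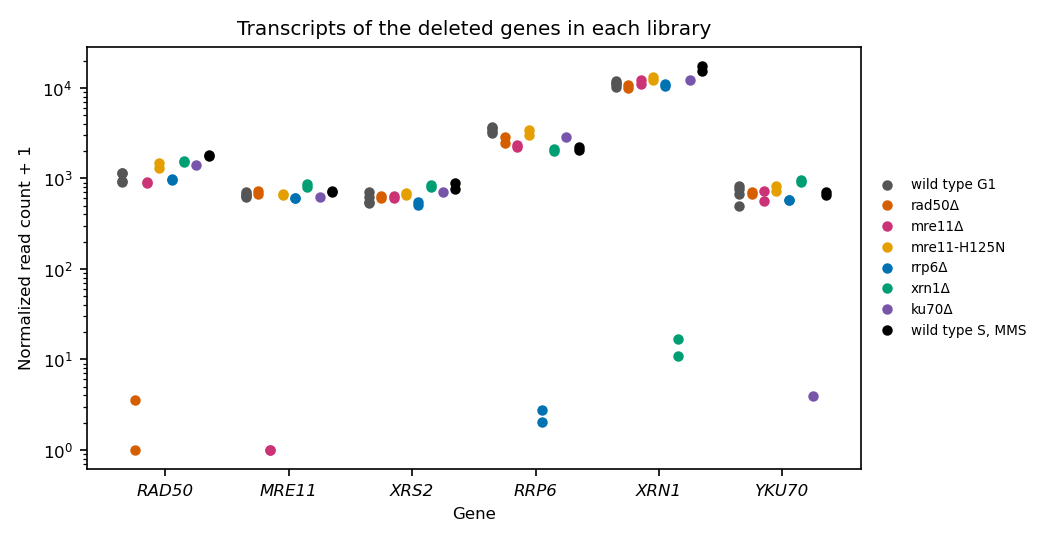
Normalized read count plus 1 (log axis) of RAD50, MRE11, XRS2, RRP6, XRN1 and YKU70, with 1 point per library coloured by group. Each deleted gene is near the floor only in its own mutant, for example XRN1 at 9.84 and 15.8 in xrn1Δ against a wild-type mean of 11149.

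In rad50Δ, 714 coding genes rose and 677 fell of 5580 tested. With TMM scaling over all classes the split was 523 higher and 1108 lower. TKL2 (YBR117C, chromosome 2, 474392 to 476437), a minor transketolase, went from 78.7 ± 30.8 in wild type to 3393 ± 490.1 in the mutant (43.1-fold, log2 5.51 ± 0.38, adjusted p = 3.77e-06). HSP26 (YBR072W, chromosome 2, 382030 to 382674), a small heat shock protein, rose 22.1-fold (log2 4.48 ± 0.17, adjusted p = 2.79e-09). EGT2 (YNL327W, chromosome 14, 24048 to 27173), which acts in the separation of daughter cells, rose 21.5-fold (log2 4.43 ± 0.16, adjusted p = 2.79e-09), and DSE4 of the same process (YNR067C, chromosome 14, 755746 to 759099) rose 16.1-fold (log2 4.02 ± 0.17, adjusted p = 8.18e-09). The stress genes GRE1 and DDR2 rose 35.9-fold (log2 5.26 ± 0.49, adjusted p = 3.52e-05) and 23.3-fold (log2 4.70 ± 0.51, adjusted p = 8.91e-05). YRO2, a membrane protein of stressed cells, rose 16.6-fold (log2 4.25 ± 0.40, adjusted p = 3.75e-05), and POT1, the peroxisomal thiolase, rose 14.4-fold (log2 3.85 ± 0.38, adjusted p = 3.77e-05). The falls were smaller. ABP140, a tRNA methyltransferase that binds actin, fell 2.64-fold (log2 -1.39 ± 0.18, adjusted p = 2.99e-04). Among genes of ribosome assembly, CGR1 fell 3.84-fold (log2 -1.71 ± 0.52, adjusted p = 0.0364) and RRP15 fell 3.31-fold (log2 -1.56 ± 0.40, adjusted p = 0.0189), and both of these calls ended when single libraries were left out.

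Stress-induced genes rose in rad50Δ: 20 of 30 rose and 0 fell (25 and 0 adjusted over the list alone), median log2 1.19, adjusted p = 8.49e-14 and adjusted p = 0.295 with an estimated correlation. SSA3, an Hsp70 of stressed cells, rose 4.31-fold (log2 2.13 ± 0.17, adjusted p = 1.02e-05). Among M/G1 daughter-cell genes, 12 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), median log2 1.92, adjusted p = 9.96e-10 and adjusted p = 0.0771 with an estimated correlation. Among G2/M genes, 12 of 25 rose and 0 fell (16 and 0 adjusted over the list alone), median log2 0.49, adjusted p = 1.76e-09 and adjusted p = 0.108 with an estimated correlation. SWI5, the activator of M/G1 genes, rose 11.5-fold (log2 3.54 ± 0.28, adjusted p = 8.93e-06), and the cyclin CLB1 rose 11.8-fold (log2 3.56 ± 0.29, adjusted p = 1.02e-05). Among DNA damage response genes, 7 of 25 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 0.48, adjusted p = 0.00162 and adjusted p = 0.108 with an estimated correlation. RNR3, the damage-inducible large subunit of ribonucleotide reductase, went from 211 ± 24.9 in wild type to 719.6 ± 45.5 in the mutant (3.41-fold, log2 1.77 ± 0.17, adjusted p = 2.64e-05). Ribosomal protein genes fell: 0 of 138 rose and 84 fell (0 and 108 adjusted over the list alone), median log2 -0.51, adjusted p = 2.34e-21 and adjusted p = 0.295 with an estimated correlation. RPL35B fell 1.98-fold (log2 -0.97 ± 0.14, adjusted p = 5.72e-04). So did ribosome biogenesis genes: 0 of 78 rose and 48 fell (0 and 64 adjusted over the list alone), median log2 -0.55, adjusted p = 7.71e-16 and adjusted p = 0.330 with an estimated correlation.

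Among nitrogen catabolite and autophagy genes of rad50Δ, 9 of 18 rose and 0 fell (12 and 0 adjusted over the list alone), median log2 0.63, adjusted p = 1.61e-05 and adjusted p = 0.125 with an estimated correlation. The ammonium permease MEP2 rose 2.66-fold (log2 1.45 ± 0.22, adjusted p = 8.09e-04) and the amino acid permease AGP1 rose 2.20-fold (log2 1.17 ± 0.20, adjusted p = 0.00213). Among Gcn4 targets, 13 of 37 rose and 0 fell (15 and 0 adjusted over the list alone), median log2 0.38, adjusted p = 4.65e-06 and adjusted p = 0.418 with an estimated correlation. LYS1 of lysine synthesis rose 2.29-fold (log2 1.22 ± 0.17, adjusted p = 5.08e-04). Among adenine and one-carbon genes, 6 of 16 rose and 0 fell (9 and 0 adjusted over the list alone), median log2 0.42, adjusted p = 4.56e-04 and adjusted p = 0.295 with an estimated correlation. GCV1 of glycine cleavage rose 3.71-fold (log2 1.91 ± 0.16, adjusted p = 1.47e-05). Among galactose genes, 5 of 12 rose and 0 fell (6 and 1 adjusted over the list alone), median log2 0.44, adjusted p = 0.00767 and adjusted p = 0.295 with an estimated correlation. GCY1, a member that encodes an aldo-keto reductase, had log2 2.14 ± 0.39, adjusted p = 0.00357. Among glycolytic genes, 1 of 19 rose and 6 fell (2 and 8 adjusted over the list alone), median log2 -0.44, adjusted p = 0.00949 and adjusted p = 0.445 with an estimated correlation. Among mitochondrially encoded genes, 11 of 18 rose and 0 fell (14 and 0 adjusted over the list alone), median log2 0.78, adjusted p = 1.91e-05 and adjusted p = 0.295 with an estimated correlation, and without the number 1 libraries 0 rose at a median of 0.68. Here and in the other strains, rows of intron-encoded genes inside COX1 and COB share reads with them. The mitochondrial rows are therefore not separate members, and camera with a preset correlation overstates their evidence. Phosphate, sulfur and iron genes gave no call (adjusted p = 0.236, 0.650 and 0.941). Their counts were 2 of 20 rose and 2 fell, 3 of 26 rose and 3 fell, and 1 of 23 rose and 1 fell.

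Genes near chromosome ends rose more often than they fell in rad50Δ. Within 20 kb of an end, 35 of 147 rose and 8 fell (37 and 10 adjusted over the list alone), median log2 0.26, adjusted p = 8.73e-04 and adjusted p = 0.295 with an estimated correlation. In the COS, PAU and YRF1 families, whose close paralogs share reads, 5 of 21 rose and 0 fell (5 and 0 adjusted over the list alone), median log2 0.36, adjusted p = 0.00289 and adjusted p = 0.295 with an estimated correlation. Among meiosis and sporulation genes, 5 of 20 rose and 0 fell (5 and 0 adjusted over the list alone), median log2 0.55, adjusted p = 0.00242 and adjusted p = 0.258 with an estimated correlation. SPS100 of the spore wall rose 11.6-fold (log2 3.51 ± 0.25, adjusted p = 3.77e-06). Gene lists were not compared with coding genes of like level. In the lowest of 10 equal bins of wild-type level, all coding genes had a median log2 of 0.59 in rad50Δ and 0.63 in mre11Δ. In both strains a general rise of weakly expressed genes thus stays open for the meiosis and chromosome-end lists. Of the α-cell markers, 2 of 3 rose and 0 fell (2 and 0 adjusted over the list alone). The α-agglutinin SAG1, normally silent in a cells, went from 324 ± 52.7 in wild type to 4135 ± 743 in the mutant (12.8-fold, log2 3.67 ± 0.21, adjusted p = 3.44e-07). Among RNA decay factors, 4 of 40 rose and 11 fell (4 and 14 adjusted over the list alone), median log2 -0.25, adjusted p = 0.00289 and adjusted p = 0.419 with an estimated correlation. The exosome subunit RRP43 had log2 -0.74 ± 0.11, adjusted p = 5.78e-04. Among nuclear pore genes, 1 of 32 rose and 5 fell (1 and 7 adjusted over the list alone), median log2 -0.18, adjusted p = 0.00821 and adjusted p = 0.445 with an estimated correlation. Mediator, MRX and end-joining, and cell wall integrity genes gave no call (adjusted p = 0.307, 0.384 and 0.119), and of the mating cassettes 0 of 2 rose and 0 fell.

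Cell cycle markers differed between libraries of the same strain. The mean of the G1/S genes, against the wild-type mean, was 1.37 log2 in the number 1 wild-type library and -0.44, -0.39 and -0.55 in the other 3. It was 1.23 and 0.22 in rad50Δ. The pheromone response genes ran opposite, at -0.97, 0.45, 0.19 and 0.34 in wild type and -0.73 and 0.20 in rad50Δ. Tested as a list, G1/S genes gave 1 of 40 rose and 0 fell (0 and 0 adjusted over the list alone), median log2 0.54, adjusted p = 0.0157 and adjusted p = 0.702 with an estimated correlation, and the list call ended without the first rad50Δ library. Histone and pheromone genes gave no call (1 of 11 rose and 0 fell, and 1 of 31 rose and 1 fell, adjusted p = 0.173 and 0.436). Without the number 1 libraries of wild type, rad50Δ and mre11Δ, a setting chosen after the data were seen, 925 coding genes changed in rad50Δ, and 17 of the 40 G1/S genes rose and 1 fell (median log2 0.51). Leaving out the first rad50Δ library gave 532 and leaving out the other gave 290.

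In mre11Δ, 676 coding genes rose and 666 fell, and with TMM scaling 579 and 828 did. TKL2 rose 25.4-fold (log2 4.73 ± 0.38, adjusted p = 1.03e-05), GRE1 rose 22.4-fold (log2 4.58 ± 0.49, adjusted p = 1.03e-04) and DDR2 rose 18.3-fold (log2 4.35 ± 0.51, adjusted p = 1.67e-04). EGT2 rose 19.2-fold (log2 4.26 ± 0.16, adjusted p = 3.46e-09), CLB1 rose 17.9-fold (log2 4.07 ± 0.29, adjusted p = 2.75e-06) and SWI5 rose 13.7-fold (log2 3.74 ± 0.28, adjusted p = 3.70e-06). YGP1, a secreted glycoprotein of starved cells, rose 9.95-fold (log2 3.57 ± 0.44, adjusted p = 3.08e-04). LOC1 (YFR001W, chromosome 6, 149110 to 149724), which acts in mRNA localization and large-subunit assembly, went from 1743 ± 359 in wild type to 584 ± 67.0 in the mutant (2.98-fold lower, log2 -1.56 ± 0.21, adjusted p = 4.32e-04). CGR1 (log2 -2.21 ± 0.52, adjusted p = 0.0124) and RRP15 (log2 -1.79 ± 0.40, adjusted p = 0.0104) of ribosome assembly fell as well, and both of their calls ended when single libraries were left out. MATALPHA2, whose sequence is shared with a silent cassette, went from 54.5 ± 21.1 in wild type to 13.2 ± 1.52 in the mutant (log2 -1.89 ± 0.35, adjusted p = 0.00301), and of the mating cassettes 0 of 2 rose and 2 fell.

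Among stress-induced genes of mre11Δ, 17 of 30 rose and 0 fell (20 and 0 adjusted over the list alone), median log2 1.00, adjusted p = 4.90e-11 and adjusted p = 0.326 with an estimated correlation. HSP26 rose 9.66-fold (log2 3.28 ± 0.17, adjusted p = 6.87e-08) and TSL1 of trehalose synthesis rose 7.14-fold (log2 2.91 ± 0.32, adjusted p = 1.43e-04). M/G1 daughter-cell genes gave 12 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), median log2 1.68, adjusted p = 4.92e-08 and adjusted p = 0.0645 with an estimated correlation. G2/M genes gave 14 of 25 rose and 0 fell (17 and 0 adjusted over the list alone), median log2 0.59, adjusted p = 5.07e-11 and adjusted p = 0.0645 with an estimated correlation, and DNA damage response genes 7 of 25 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 0.47, adjusted p = 2.96e-04 and adjusted p = 0.0645 with an estimated correlation. RNR3 went from 211 ± 24.9 in wild type to 781 ± 229 in the mutant (3.70-fold, log2 1.86 ± 0.17, adjusted p = 1.54e-05). Ribosomal protein genes fell: 0 of 138 rose and 84 fell (0 and 110 adjusted over the list alone), median log2 -0.50, adjusted p = 1.01e-20 and adjusted p = 0.326 with an estimated correlation. RPL31A had log2 -0.79 ± 0.13, adjusted p = 0.00149. Ribosome biogenesis genes fell: 0 of 78 rose and 43 fell (0 and 63 adjusted over the list alone), median log2 -0.55, adjusted p = 5.48e-16 and adjusted p = 0.327 with an estimated correlation. The assembly factors RPF2 (log2 -0.76 ± 0.14, adjusted p = 0.00244) and RLP7 (log2 -0.98 ± 0.18, adjusted p = 0.00265) were examples.

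G1/S genes rose in the mre11Δ test: 9 of 40 rose and 0 fell (14 and 0 adjusted over the list alone), median log2 1.25, adjusted p = 8.81e-07 and adjusted p = 0.434 with an estimated correlation. Histone genes gave 8 of 11 rose and 0 fell (10 and 0 adjusted over the list alone), median log2 1.07, adjusted p = 3.03e-04 and adjusted p = 0.399 with an estimated correlation. Both list calls ended without the first mre11Δ library. The means of the 2 mre11Δ libraries were 2.51 and 0.54 for G1/S genes and 2.20 and 0.33 for histones. RFA1, the large subunit of replication protein A, rose 3.80-fold (log2 1.93 ± 0.33, adjusted p = 0.00224). Pheromone genes stood at -1.79 and 0.18 in these libraries: 0 of 31 rose and 1 fell (0 and 1 adjusted over the list alone), median log2 -0.82, adjusted p = 0.00490 and adjusted p = 0.612 with an estimated correlation. Without the first library their median was 0.147. Without the number 1 libraries of wild type, rad50Δ and mre11Δ, 821 coding genes changed in mre11Δ and 24 of the 40 G1/S genes rose (median log2 0.74), and without the first mre11Δ library alone 596 did.

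Nitrogen catabolite genes rose in mre11Δ: 10 of 18 rose and 0 fell (10 and 0 adjusted over the list alone), median log2 0.43, adjusted p = 9.76e-06 and adjusted p = 0.113 with an estimated correlation. MEP2 rose 3.77-fold (log2 1.94 ± 0.22, adjusted p = 9.82e-05) and the general amino acid permease GAP1 rose 2.87-fold (log2 1.56 ± 0.22, adjusted p = 4.64e-04). Among adenine and one-carbon genes, 7 of 16 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 0.37, adjusted p = 0.00124 and adjusted p = 0.326 with an estimated correlation. Among galactose genes, 5 of 12 rose and 1 fell (9 and 1 adjusted over the list alone), median log2 0.68, adjusted p = 0.00464 and adjusted p = 0.326 with an estimated correlation. Among Gcn4 targets, 7 of 37 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 0.26, adjusted p = 6.15e-04 and adjusted p = 0.471 with an estimated correlation. Among phosphate genes, 4 of 20 rose and 0 fell (6 and 0 adjusted over the list alone), median log2 0.28, adjusted p = 0.0350 and adjusted p = 0.434 with an estimated correlation. GIT1, a glycerophosphoinositol transporter, rose 3.41-fold (log2 1.77 ± 0.14, adjusted p = 5.03e-06). Among mitochondrially encoded genes, 11 of 18 rose and 1 fell (13 and 1 adjusted over the list alone), median log2 0.77, adjusted p = 7.22e-05 and adjusted p = 0.327 with an estimated correlation, and without the number 1 libraries 1 rose at a median of 0.76.

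Meiosis genes of mre11Δ gave 6 of 20 rose and 1 fell (6 and 2 adjusted over the list alone), median log2 0.40, adjusted p = 0.0213 and adjusted p = 0.326 with an estimated correlation. Cell wall integrity genes gave 6 of 16 rose and 0 fell (8 and 0 adjusted over the list alone), median log2 0.39, adjusted p = 0.0213 and adjusted p = 0.399 with an estimated correlation. The wall protein SED1 had log2 1.69 ± 0.24, adjusted p = 5.72e-04. Within 20 kb of an end, 27 of 147 rose and 4 fell (27 and 4 adjusted over the list alone), median log2 0.23, adjusted p = 0.00128 and adjusted p = 0.326 with an estimated correlation. RNA decay factors gave 3 of 40 rose and 9 fell (4 and 11 adjusted over the list alone), median log2 -0.22, adjusted p = 0.00238 and adjusted p = 0.406 with an estimated correlation, with the deadenylase CCR4 on the rising side (log2 1.28 ± 0.13, adjusted p = 5.91e-05). SAG1 rose 7.64-fold (log2 2.87 ± 0.21, adjusted p = 3.70e-06), and of the α-cell markers 2 of 3 rose and 0 fell. The glycolytic, sulfur, iron, Mediator, nuclear pore, subtelomeric family and MRX lists gave no call (adjusted p = 0.0918, 0.984, 0.540, 0.0509, 0.135, 0.0803 and 0.984).

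**Figure D2:**
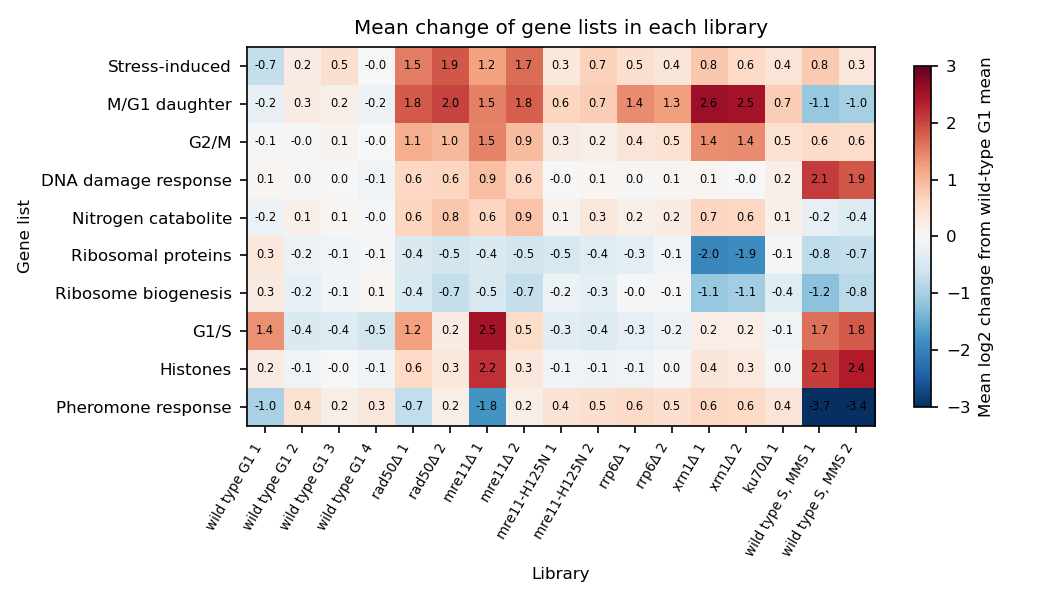
Mean log2 change of 10 gene lists (rows) in each of the 17 libraries (columns), against the mean of the 4 wild-type G1 libraries. Stress genes lie at 1.21 to 1.86 in the rad50Δ and mre11Δ libraries, against -0.72 to 0.48 in wild type. They lie above 0 in the other mutant and MMS libraries too (0.31 to 0.81). G1/S genes reach 1.37 in the first wild-type library and 2.51 in the first mre11Δ library.

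Between rad50Δ and mre11Δ, 4 coding genes were higher and 5 lower in rad50Δ, and 397 passed an unadjusted p of 0.05. Besides RAD50 and MRE11 they were the marker genes URA3 and LEU2, HSP26 (adjusted p = 0.0232) and GIT1 (log2 -2.26, adjusted p = 5.58e-06), and DRS2 (log2 -0.84, adjusted p = 0.00623), APA1 and SLH1, named after their values were seen. Without the second mre11Δ library 110 coding genes differed, and a replicate block over 6 libraries, chosen after the data were seen, gave 63, against 4 in the same 6 without the block. edgeR called 8 and DESeq2 54 coding genes here. Against wild type, 492 genes rose in both deletions, 449 fell in both and 1 moved in opposite directions. Independent calls would give 86.6 and 80.3. The changes correlated at r = 0.884 over 5568 genes, which are not independent replicates. Both used the same controls, for which simulated data without any effect gave r = 0.340, and with separate wild-type libraries r was 0.621 and 0.769. The simulation ignores that same-numbered libraries of these groups deviated together, and single libraries that shared neither control nor number gave r = 0.719 and 0.598. The covariance was 0.351, against 0.0189 in the simulation. Averaged over both deletions, 935 coding genes rose and 1008 fell.

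In mre11-H125N, 58 coding genes rose and 23 fell. EGT2 rose 4.27-fold (log2 2.10 ± 0.16, adjusted p = 2.54e-05) and DSE4 rose 2.60-fold (log2 1.39 ± 0.17, adjusted p = 0.00103), as did YFR016C, an uncharacterized gene (2.57-fold, log2 1.37 ± 0.16, adjusted p = 0.00100). IMD2 (YHR216W, chromosome 8, 554396 to 555967), an IMP dehydrogenase of guanine nucleotide synthesis, went from 8020.4 ± 698 in wild type to 3569.7 ± 173 in the mutant (2.25-fold lower, log2 -1.16 ± 0.12, adjusted p = 4.46e-04). GAR1, a protein of H/ACA snoRNPs, fell 2.49-fold (log2 -1.32 ± 0.24, adjusted p = 0.0192). The vitamin B6 gene SNZ1 rose 3.96-fold (log2 2.05 ± 0.35, adjusted p = 0.0170) and ADE17 of purine synthesis rose 3.24-fold (log2 1.77 ± 0.30, adjusted p = 0.0159). SAG1 rose 2.42-fold (log2 1.29 ± 0.21, adjusted p = 0.0124). Of these genes, only EGT2, DSE4, YFR016C and IMD2 kept the call without the first H125N library, which left 6 coding genes, against 284 without the other. DESeq2 called 684 coding genes and edgeR 94, and against the first 2 wild-type libraries alone, a setting chosen after the data were seen, limma called 962.

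M/G1 daughter-cell genes of mre11-H125N gave 3 of 17 rose and 0 fell (5 and 0 adjusted over the list alone), median log2 0.59, adjusted p = 1.81e-04 and adjusted p = 0.642 with an estimated correlation. Adenine and one-carbon genes gave 3 of 16 rose and 0 fell (10 and 2 adjusted over the list alone), median log2 0.48, adjusted p = 1.66e-04 and adjusted p = 0.642 with an estimated correlation. Ribosomal protein genes gave 0 of 138 rose and 3 fell (0 and 95 adjusted over the list alone), median log2 -0.41, adjusted p = 3.15e-25 and adjusted p = 0.652 with an estimated correlation. Ribosome biogenesis genes gave 0 of 78 rose and 2 fell (0 and 3 adjusted over the list alone), median log2 -0.25, adjusted p = 1.77e-05 and adjusted p = 0.837 with an estimated correlation. Mitochondrially encoded genes gave 0 of 18 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 0.51, adjusted p = 2.56e-05 and adjusted p = 0.652 with an estimated correlation. Stress-induced genes gave 1 of 30 rose and 0 fell (1 and 0 adjusted over the list alone), median log2 0.50, adjusted p = 2.82e-04 and adjusted p = 0.797 with an estimated correlation, a call that other settings ended. The DNA damage response list gave no call (0 of 25 rose and 0 fell, median log2 -0.04, adjusted p = 0.619).

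Tested directly, 481 coding genes were higher and 433 lower in mre11Δ than in mre11-H125N. Without the first H125N library 162 differed, and with only the groups compared 327. Depth differed as well, with 7512010 and 9003630 reads in mre11Δ against 32942688 and 30777111 in mre11-H125N. Wild type 1 and 2 differed from 3 and 4 too, for example in iron genes (list means 0.82 and 0.41 against -0.37 and -0.86). Neither this comparison nor that of the average of both deletions has wild type as control. A difference between sets of libraries could therefore not be told from that of genotype. TKL2 (log2 3.68, adjusted p = 5.37e-04), HSP26 (log2 2.94, adjusted p = 4.89e-06) and EGT2 (log2 2.17, adjusted p = 4.10e-05) were higher. So were RNR3 (log2 1.71, adjusted p = 2.67e-04) and MEP2 (log2 1.70, adjusted p = 0.00127). Of the G2/M genes, 13 of 25 were higher in mre11Δ (median log2 0.73, adjusted p = 1.59e-07 and adjusted p = 0.230 with an estimated correlation). Of the stress genes, 11 of 30 were (median log2 0.71, adjusted p = 3.37e-05 and adjusted p = 0.706 with an estimated correlation). The average of both deletions differed from mre11-H125N at 661 higher and 608 lower coding genes, and at 238 in all without the first H125N library. The changes of rad50Δ and mre11-H125N correlated at r = 0.336 (simulated 0.332, separate controls 0.314 and 0.0131, covariance 0.0856 against 0.0184 simulated). For mre11Δ and mre11-H125N r was 0.212 (simulated 0.328, separate controls 0.276 and -0.118, covariance 0.0559 against 0.0181).

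**Figure D3:**
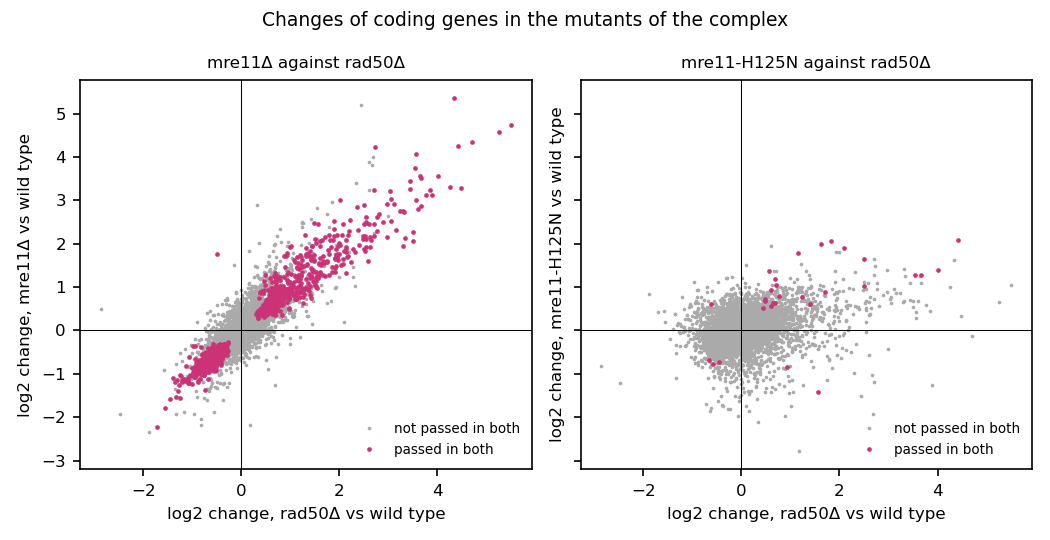
Log2 change against wild type of coding genes in mre11Δ (left) and mre11-H125N (right) against that in rad50Δ, with 1 point per gene and genes past the threshold in both comparisons in colour. The left panel follows a diagonal (r = 0.884), the right panel less so (r = 0.336), with shared wild-type libraries in both.

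Unstable transcripts also moved in rad50Δ. Among XUTs, which accumulate without Xrn1, 223 of 1424 rose and 33 fell, median log2 0.34, adjusted p = 9.94e-06 and adjusted p = 0.0639 with an estimated correlation. Among CUTs, which the nuclear exosome degrades, 78 of 760 rose and 14 fell, median log2 0.29, adjusted p = 9.52e-04 and adjusted p = 0.220 with an estimated correlation, and among SUTs, stable unannotated transcripts, 126 of 734 rose and 17 fell, median log2 0.32, adjusted p = 9.94e-06 and adjusted p = 0.0639 with an estimated correlation. XUT1625 (chromosome 14, 462231 to 466625) rose 4.34-fold (log2 2.11 ± 0.18, adjusted p = 1.21e-05) and CUT904 (chromosome 16, 518073 to 518553) rose 7.82-fold (log2 2.90 ± 0.31, adjusted p = 7.01e-05). The classes overlap each other in part, so some reads count in more than 1 of them. Here and in the other strains they were not compared with coding genes of like level. In mre11Δ the medians were smaller and no class of these 3 was called. Its XUTs gave 158 of 1424 rose and 63 fell, median log2 0.13, adjusted p = 0.142 and adjusted p = 0.787 with an estimated correlation, its CUTs a median log2 of 0.06 (adjusted p = 0.460) and its SUTs 0.12 (adjusted p = 0.142). With 6 libraries its XUT and SUT medians, 0.22 and 0.17, were called with a replicate block (adjusted p = 0.0108 and 0.0122) and without it (adjusted p = 0.00529 and 0.00612), but with an estimated correlation neither was (adjusted p = 0.168 and 0.226 with the block, 0.352 and 0.403 without it). The XUT class as a whole lay higher in rad50Δ than in mre11Δ, though few members passed (3 of 1424 higher and 1 lower, median log2 0.22, adjusted p = 3.73e-05 and adjusted p = 0.0842 with an estimated correlation). So did CUTs (median log2 0.21, adjusted p = 3.96e-05 and adjusted p = 0.117 with an estimated correlation) and SUTs (median log2 0.18, adjusted p = 1.83e-05 and adjusted p = 0.0842 with an estimated correlation). In mre11-H125N no class of these 3 was called (XUTs 29 higher and 3 lower, median log2 0.09, adjusted p = 0.141).

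In rrp6Δ the CUT, XUT and SUT classes rose. Among CUTs, 650 of 760 rose and 4 fell, median log2 2.63, adjusted p = 2.32e-89 and adjusted p = 1.59e-05 with an estimated correlation, a median of 6.17-fold. CUT841 (chromosome 15, 409158 to 409566) went from 26.1 ± 7.13 in wild type to 2696 ± 263 in the mutant (103-fold, log2 6.68 ± 0.26, adjusted p = 7.64e-09). CUT306 (chromosome 13, 652602 to 652922) went from 99.5 ± 50.6 in wild type to 5489 ± 782 in the mutant (55.2-fold, log2 5.89 ± 0.32, adjusted p = 8.67e-08). Among XUTs, 857 of 1424 rose and 24 fell, median log2 1.19, adjusted p = 9.10e-48 and adjusted p = 2.10e-05 with an estimated correlation. Among SUTs, 428 of 734 rose and 7 fell, median log2 0.97, adjusted p = 2.79e-43 and adjusted p = 2.10e-05 with an estimated correlation, and among windows divergent from promoters, 427 of 1946 rose and 50 fell, median log2 0.31, adjusted p = 1.04e-08 and adjusted p = 0.0190 with an estimated correlation. Among tRNAs, 42 of 85 rose and 3 fell, median log2 1.29, adjusted p = 4.77e-17 and adjusted p = 0.0504 with an estimated correlation, and among snoRNAs, 26 of 77 rose and 12 fell, median log2 0.05, adjusted p = 0.0109 and adjusted p = 0.536 with an estimated correlation. Of 14 rRNA rows, 0 rose and 5 fell. SNR71 rose 29.0-fold (log2 4.86 ± 0.25, adjusted p = 5.67e-08), and SRG1, a noncoding RNA across the SER3 promoter, rose 2.12-fold (log2 1.08 ± 0.13, adjusted p = 4.36e-05).

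Among coding genes of rrp6Δ, 482 rose and 513 fell. MIP6, an RNA-binding protein, rose 7.28-fold (log2 2.92 ± 0.24, adjusted p = 2.16e-06), and IMD2 fell 1.92-fold (log2 -0.94 ± 0.12, adjusted p = 7.69e-05). EGT2 rose 7.47-fold (log2 2.90 ± 0.16, adjusted p = 1.22e-07), DSE2 rose 10.5-fold (log2 3.59 ± 0.41, adjusted p = 4.51e-05) and the chitinase CTS1 rose 6.31-fold (log2 2.75 ± 0.34, adjusted p = 9.60e-05), all of cell separation. NRD1, which hands short noncoding transcripts to the exosome, rose 3.62-fold (log2 1.88 ± 0.18, adjusted p = 8.51e-06). The acid phosphatase PHO5 fell 13.3-fold (log2 -3.60 ± 0.34, adjusted p = 1.06e-05). In leucine synthesis and transport, BAT1 fell 9.36-fold (log2 -3.21 ± 0.14, adjusted p = 1.60e-08), LEU1 fell 6.53-fold (log2 -2.70 ± 0.15, adjusted p = 8.67e-08) and OAC1 fell 8.09-fold (adjusted p = 1.65e-08). The marker LEU2 stood at 411 and 553 in the same libraries, against 2774 ± 269 in wild type.

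Sulfur genes fell in rrp6Δ: 0 of 26 rose and 16 fell (0 and 17 adjusted over the list alone), median log2 -0.90, adjusted p = 4.69e-11 and adjusted p = 0.474 with an estimated correlation. MET5 had log2 -1.59 ± 0.15, adjusted p = 7.22e-06. Glycolytic genes gave 0 of 19 rose and 12 fell (0 and 14 adjusted over the list alone), median log2 -0.49, adjusted p = 5.00e-07 and adjusted p = 0.474 with an estimated correlation, with TDH2 at log2 -1.21 ± 0.20, adjusted p = 4.33e-04. M/G1 genes gave 9 of 17 rose and 0 fell (9 and 0 adjusted over the list alone), median log2 1.11, adjusted p = 1.39e-07 and adjusted p = 0.149 with an estimated correlation. Gcn4 targets gave 2 of 37 rose and 12 fell (2 and 13 adjusted over the list alone), median log2 -0.35, adjusted p = 1.20e-04 and adjusted p = 0.634 with an estimated correlation, and G2/M genes 8 of 25 rose and 0 fell (8 and 0 adjusted over the list alone), median log2 0.34, adjusted p = 6.51e-04 and adjusted p = 0.474 with an estimated correlation. With TMM scaling over all classes the split of coding genes was 174 higher and 1871 lower. Leaving out either rrp6Δ library gave 343 and 390 coding genes.

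**Figure D4:**
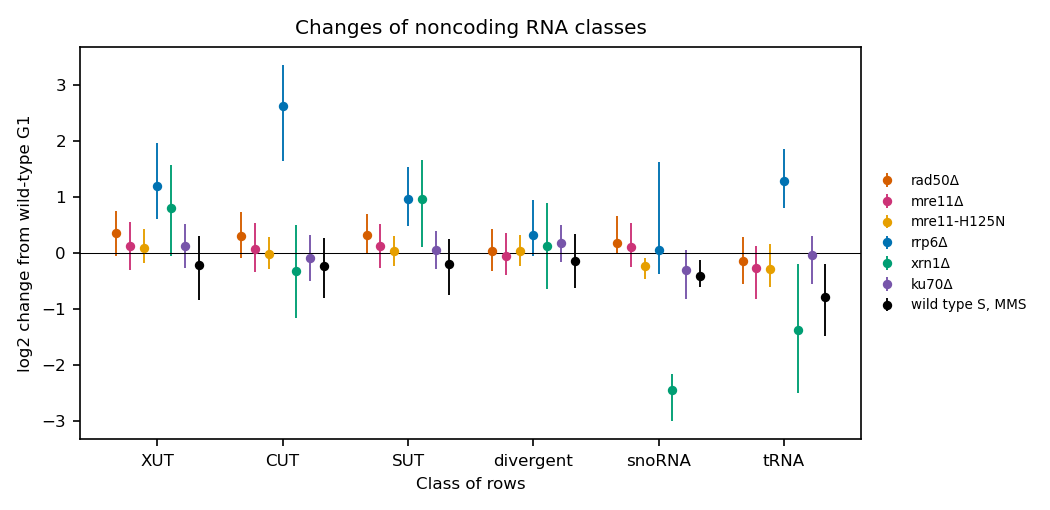
Median log2 change from wild-type G1 (points) with quartiles (bars) of 6 RNA classes in each mutant or condition. CUTs stand at 2.63 in rrp6Δ and snoRNAs at -2.46 in xrn1Δ.

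In xrn1Δ most mitochondrially encoded transcripts were almost gone: 0 of 18 rose and 18 fell (0 and 18 adjusted over the list alone), median log2 -10.77, adjusted p = 7.42e-17 and adjusted p = 0.161 with an estimated correlation. These are coding rows, and those of intron-encoded genes inside COX1 and COB share reads with them. COX1 (Q0045, chromosome mt, 13818 to 26701), a subunit of cytochrome oxidase, went from 122907 ± 29716 in wild type to 68.8 ± 17.9 in the mutant (log2 -10.78 ± 0.22, adjusted p = 2.32e-13). COB, cytochrome b, went from 29434 ± 7525 in wild type to 11.7 ± 1.08 in the mutant (log2 -11.14 ± 0.22, adjusted p = 2.32e-13). The mitochondrial ribosomal RNA 21S_RRNA went from 236579 ± 26092 in wild type to 92.7 ± 33.2 in the mutant (log2 -11.34 ± 0.24, adjusted p = 4.01e-13). Q0092, a dubious row of the same genome (30874 to 31014), went the other way, from a wild-type mean of 2.27 to 286 and 379 (adjusted p = 7.56e-06). In all, 1961 coding genes rose and 1831 fell. EGT2 rose 43.5-fold (log2 5.44 ± 0.16, adjusted p = 1.97e-11) and CLB1 rose 21.3-fold (log2 4.41 ± 0.29, adjusted p = 5.32e-08). DSE4 rose 19.8-fold (log2 4.32 ± 0.17, adjusted p = 3.89e-10) and DSE2 rose 11.8-fold (log2 3.79 ± 0.41, adjusted p = 6.33e-06). Ribosomal protein genes fell: 1 of 138 rose and 135 fell (2 and 135 adjusted over the list alone), median log2 -2.02, adjusted p = 6.76e-34 and adjusted p = 0.304 with an estimated correlation. RPS8A fell 5.82-fold (log2 -2.53 ± 0.12, adjusted p = 5.21e-09).

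**Figure D5:**
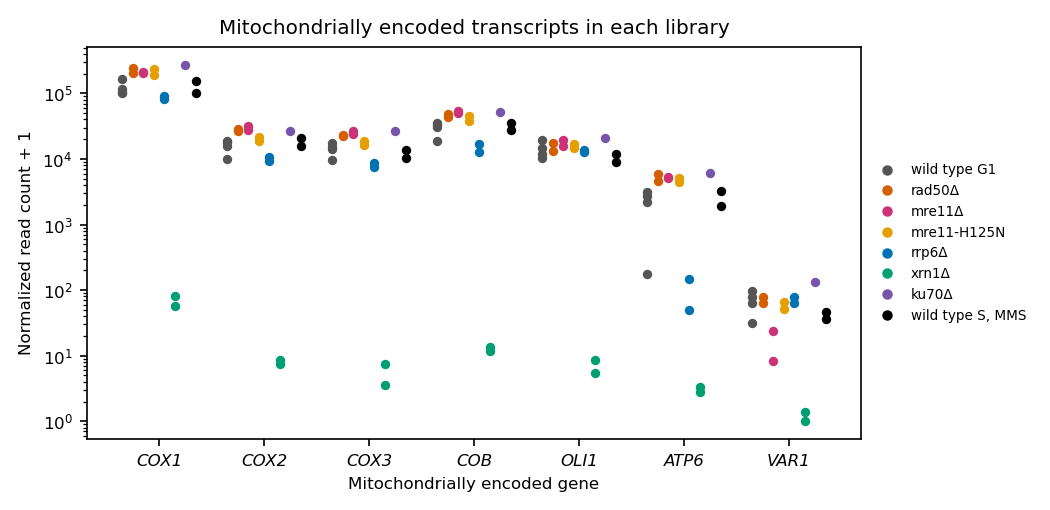
Normalized read count plus 1 (log axis) of 7 mitochondrially encoded genes, with 1 point per library coloured by group. The xrn1Δ libraries lie far below the others, for COX1 at a mean of 68.8 against 122907 in wild type.

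Ribosome biogenesis genes fell in xrn1Δ: 0 of 78 rose and 67 fell (0 and 67 adjusted over the list alone), median log2 -1.08, adjusted p = 5.78e-13 and adjusted p = 0.406 with an estimated correlation. GAR1 had log2 -3.43 ± 0.24, adjusted p = 9.62e-08. Glycolytic genes gave 1 of 19 rose and 16 fell (1 and 16 adjusted over the list alone), median log2 -1.32, adjusted p = 3.23e-05 and adjusted p = 0.390 with an estimated correlation, and pyruvate decarboxylase PDC1 fell 4.36-fold (log2 -2.12 ± 0.16, adjusted p = 1.63e-07). Gcn4 targets gave 4 of 37 rose and 29 fell (4 and 30 adjusted over the list alone), median log2 -1.40, adjusted p = 7.47e-07 and adjusted p = 0.406 with an estimated correlation, and sulfur genes 2 of 26 rose and 21 fell (2 and 21 adjusted over the list alone), median log2 -1.55, adjusted p = 3.23e-05 and adjusted p = 0.406 with an estimated correlation. M/G1 genes rose: 15 of 17 rose and 0 fell (15 and 0 adjusted over the list alone), median log2 2.47, adjusted p = 2.23e-05 and adjusted p = 0.161 with an estimated correlation. G2/M genes gave 19 of 25 rose and 0 fell (19 and 0 adjusted over the list alone), median log2 1.12, adjusted p = 8.32e-06 and adjusted p = 0.256 with an estimated correlation. MRX and end-joining genes gave 15 of 19 rose and 1 fell (15 and 1 adjusted over the list alone), median log2 0.57, adjusted p = 0.00105 and adjusted p = 0.161 with an estimated correlation, and the checkpoint kinase TEL1 rose 2.98-fold (log2 1.59 ± 0.12, adjusted p = 1.76e-07). Within 20 kb of an end, 73 of 147 rose and 24 fell (73 and 24 adjusted over the list alone), median log2 0.64, adjusted p = 0.00136 and adjusted p = 0.406 with an estimated correlation. DNA damage response genes gave no list call (12 of 25 rose and 6 fell, median log2 0.33, adjusted p = 0.701), and RNR2 fell 5.40-fold (log2 -2.42 ± 0.14, adjusted p = 2.14e-08). DHH1, an activator of decapping, rose 3.29-fold (log2 1.72 ± 0.09, adjusted p = 1.68e-08), and the exosome helicase MTR4 had log2 -1.62 ± 0.15, adjusted p = 7.23e-07.

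Among XUTs of xrn1Δ, 694 of 1424 rose and 148 fell, median log2 0.79, adjusted p = 1.64e-06 and adjusted p = 0.0486 with an estimated correlation, and among SUTs, 411 of 734 rose and 71 fell, median log2 0.96, adjusted p = 1.78e-08 and adjusted p = 0.0312 with an estimated correlation. XUT0471 (chromosome 9, 34908 to 37311) rose 5.02-fold (log2 2.32 ± 0.11, adjusted p = 4.47e-09). CUTs gave no call (110 of 760 rose and 213 fell, median log2 -0.32, adjusted p = 0.108 and adjusted p = 0.495 with an estimated correlation). Among snoRNAs, 0 of 77 rose and 75 fell, median log2 -2.46, adjusted p = 2.39e-21 and adjusted p = 0.0730 with an estimated correlation. SNR31 fell 7.94-fold (log2 -2.98 ± 0.12, adjusted p = 9.30e-10). Among tRNAs, 8 of 85 rose and 49 fell, median log2 -1.37, adjusted p = 7.81e-05 and adjusted p = 0.430 with an estimated correlation. The telomerase RNA TLC1 fell 6.17-fold (log2 -2.59 ± 0.17, adjusted p = 6.56e-08). ICR1, a noncoding RNA upstream of FLO11, rose 5.52-fold (log2 2.48 ± 0.17, adjusted p = 6.63e-08). All of these changes are relative, since values were scaled by 1 size factor per library. The normalized total over ORF rows was also lower in both xrn1Δ libraries than in every wild-type library. Whether selection of RNA classes during library preparation contributed to the falls of snoRNAs, tRNAs and TLC1 was not tested. The change of coding genes went down with wild-type level. Over 10 equal bins the median log2 change was 0.76 in the lowest bin, 0.09 in the sixth and -0.15 in the seventh. It was -1.55 in the highest, 2.31 below the lowest. The gene lists of xrn1Δ were not compared with coding genes of like level. Falls of lists of abundant genes, such as glycolytic and ribosomal protein genes, were thus not separated from this trend.

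In the single ku70Δ library, assumed to vary like the other groups, 24 coding genes rose and 20 fell. The sulfite pump SSU1 rose 5.30-fold (log2 2.46 ± 0.32, adjusted p = 0.00235) and SAG1 rose 4.35-fold (log2 2.13 ± 0.27, adjusted p = 0.00220). SWI5 rose 4.20-fold (log2 2.10 ± 0.36, adjusted p = 0.0180), DSE4 rose 3.92-fold (log2 1.99 ± 0.21, adjusted p = 3.79e-04) and EGT2 rose 3.74-fold (log2 1.91 ± 0.21, adjusted p = 4.93e-04). The checkpoint target HUG1 rose 3.81-fold (log2 1.89 ± 0.34, adjusted p = 0.0221). THI5, which has close paralogs in thiamine synthesis, rose 4.22-fold (log2 2.05 ± 0.36, adjusted p = 0.0190). OAC1 fell 6.83-fold (log2 -2.76 ± 0.17, adjusted p = 1.67e-06), LEU1 fell 5.48-fold (log2 -2.45 ± 0.19, adjusted p = 1.45e-05) and BAT1 fell 4.60-fold (log2 -2.18 ± 0.18, adjusted p = 2.08e-05), and LEU2 stood at 519. The 18 mitochondrially encoded rows had a median log2 of 0.97. Rows of intron-encoded genes share reads with COX1 and COB, so these are not separate members. M/G1 genes gave 2 of 17 rose and 0 fell (5 and 0 adjusted over the list alone), median log2 0.75, adjusted p = 1.54e-04 and adjusted p = 0.334 with an estimated correlation, and genes within 20 kb of an end 2 of 147 rose and 0 fell (5 and 1 adjusted over the list alone), median log2 0.15, adjusted p = 0.00720 and adjusted p = 0.507 with an estimated correlation. Without the number 3 wild-type library 127 coding genes changed, and against the first 2 wild-type libraries alone, a setting chosen after the data were seen, 379.

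In S phase with MMS, 1312 coding genes rose and 1310 fell, with cell cycle stage, arrest and MMS changing together, and without the first MMS library 1624 coding genes changed. The glutathione peroxidase GPX2 (YBR244W, chromosome 2, 707528 to 708016) went from 237 ± 8.23 in wild type to 10441 ± 175 in MMS (44.1-fold, log2 5.46 ± 0.10, adjusted p = 7.45e-13). Among DNA damage response genes, 19 of 25 rose and 0 fell (20 and 0 adjusted over the list alone), median log2 1.71, adjusted p = 1.79e-09 and adjusted p = 0.00677 with an estimated correlation. RNR3 rose 16.5-fold (log2 4.03 ± 0.17, adjusted p = 3.51e-09) and HUG1 rose 22.0-fold (log2 4.36 ± 0.26, adjusted p = 7.23e-08). Pheromone genes fell: 0 of 31 rose and 31 fell (0 and 31 adjusted over the list alone), median log2 -3.61, adjusted p = 1.39e-14 and adjusted p = 0.445 with an estimated correlation. The a-factor exporter STE6 fell 10.1-fold (log2 -3.33 ± 0.17, adjusted p = 2.36e-08), the a-factor gene MFA1 fell 48.7-fold (log2 -5.57 ± 0.30, adjusted p = 5.68e-08) and the cell fusion gene FUS1 fell 24.4-fold (log2 -4.46 ± 0.70, adjusted p = 4.32e-04). BAR1, the protease that degrades α-factor, fell 35.9-fold (log2 -5.13 ± 0.44, adjusted p = 5.27e-06). G1/S genes gave 24 of 40 rose and 2 fell (26 and 2 adjusted over the list alone), median log2 1.88, adjusted p = 3.26e-05 and adjusted p = 0.850 with an estimated correlation. RFA2 of replication protein A rose 6.66-fold (log2 2.86 ± 0.37, adjusted p = 1.02e-04). Histone genes gave 10 of 11 rose and 0 fell (10 and 0 adjusted over the list alone), median log2 2.00, adjusted p = 3.26e-05 and adjusted p = 0.528 with an estimated correlation, with HHT2 at log2 2.00 ± 0.21, adjusted p = 1.20e-05.

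M/G1 genes fell in MMS: 1 of 17 rose and 9 fell (1 and 10 adjusted over the list alone), median log2 -0.90, adjusted p = 0.0139 and adjusted p = 0.445 with an estimated correlation. Ribosome biogenesis genes gave 0 of 78 rose and 77 fell (0 and 77 adjusted over the list alone), adjusted p = 2.47e-20 and adjusted p = 0.445 with an estimated correlation, and ribosomal protein genes 0 of 138 rose and 130 fell (0 and 133 adjusted over the list alone), median log2 -0.73, adjusted p = 2.12e-22 and adjusted p = 0.445 with an estimated correlation. Gcn4 targets gave 26 of 37 rose and 1 fell (29 and 1 adjusted over the list alone), median log2 0.68, adjusted p = 2.53e-07 and adjusted p = 0.536 with an estimated correlation. Cell wall integrity genes gave 1 of 16 rose and 13 fell (1 and 13 adjusted over the list alone), median log2 -1.57, adjusted p = 2.25e-04 and adjusted p = 0.445 with an estimated correlation. The stress-induced list gave 13 of 30 rose and 2 fell (15 and 2 adjusted over the list alone), median log2 0.57, adjusted p = 0.0253 and adjusted p = 0.981 with an estimated correlation, and the thioredoxin TRX2 rose 7.39-fold (log2 2.88 ± 0.14, adjusted p = 2.14e-08). The iron transport gene FIT2 rose 19.3-fold (log2 4.59 ± 0.56, adjusted p = 6.09e-05) and cytochrome c, CYC1, fell 30.6-fold (log2 -4.85 ± 0.31, adjusted p = 3.03e-07). The XUT, CUT and SUT medians were -0.23, -0.25 and -0.20 (adjusted p = 0.0250, 0.0476 and 0.0248, and adjusted p = 0.408 with an estimated correlation for each).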

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

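Items were marked by rules fixed beforehand, while the test without the number 1 libraries was chosen after the results were seen and those of splits and depth before theirs were. Among the 4 wild-type libraries, Dixon's gap ratio marked the first for the mean of the G1/S genes (gap ratio 0.917) and for RNR1, the large subunit of ribonucleotide reductase (0.936, 15604 normalized reads against 769 to 933 in the others). The same library was marked for RFA2 of replication protein A (0.865), the pheromone-induced FUS1 (0.862) and BAR1 (0.868), IMD2 (0.854) and OAC1 (0.911). DSE2 was marked in the number 2 library (0.945), and HIS3 (0.992) and CUT841 (0.917) in the number 3 library. Chance flags about 1 in 20 groups, and 109 genes and 35 lists or classes were tested.

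A difference between groups was marked for 914 coding genes between mre11Δ and mre11-H125N, and for 1269 between the average of the MRX deletions and mre11-H125N, with 162 and 238 left without the first H125N library. Depth differed between these groups as well, and neither comparison has wild type as control. The stress genes TKL2 and HSP26, the damage gene RNR3 and the separation gene EGT2 were among the genes higher in the deletion.

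The changes shared by rad50Δ and mre11Δ were weighed against 3 technical explanations: with 8 libraries (4 wild type, 4 deletions), the real split called 1313 coding genes and was 1 of 35 splits to do so, with 0 in the highest other split (2176 and at most 985 at unadjusted p under 0.05), so the real grouping stood apart from every other. Weaker arrest in the number 1 libraries would take the changes away with those libraries. Without them the medians of the stress, daughter-cell, ribosome and DNA damage lists kept at least 88.8% of their size. The median of the G1/S genes kept 73.6% (44.5% to 97.5%, 95% interval). That interval is over the 40 genes, which move together. With 1 library left of each deletion, it does not measure the spread between libraries. These medians thus did not rest on the number 1 libraries alone. The histone and pheromone lists kept 55.7% and 20.2%, so weaker arrest stays open for them. Leaving out the number 1 libraries cannot test a weaker arrest of the deletion strains themselves. In the second libraries of rad50Δ and mre11Δ the G1/S mean was 0.22 and 0.54 log2, against -0.44, -0.39 and -0.55 in wild type 2 to 4. Lower depth of the deletion libraries would end the calls on thinning all libraries, where 88.5% of the called genes were kept. Loss of the MRX complex remains a possible cause, but each genotype is 1 strain in the labels and a second difference between strains could have contributed. The rise of the daughter-cell genes was not particular to these deletions. Their list means were 0.64 and 0.73 log2 in mre11-H125N, 1.41 and 1.26 in rrp6Δ, 2.56 and 2.51 in xrn1Δ and 0.73 in ku70Δ. A difference of the wild-type libraries from all mutants thus stays open for them. G2/M means were above wild type (-0.05 to 0.09) in mre11-H125N (0.25 and 0.18), rrp6Δ (0.395 and 0.466), xrn1Δ (1.397 and 1.425) and ku70Δ (0.47). In the deletions they were 0.934 to 1.498. Ribosomal protein means were about as low in mre11-H125N (-0.48 and -0.37) as in the deletions (-0.55 to -0.42). They were -1.96 and -1.89 in xrn1Δ, -0.27 and -0.09 in rrp6Δ, -0.05 in ku70Δ and -0.17 to 0.31 in wild type. Neither change was thus particular to the deletions.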

How the results depend on the processing

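Each alternative changed 1 choice, with exceptions. The block over 6 libraries also left out the others. The edgeR and DESeq2 fits also took the recovered whole reads as input and gave no ku70Δ count. Alternatives named as added were chosen after seeing the data. Over 630 values in the text and tables, 11525 alternative values were computed: 10497 stayed on the same side of the threshold with the same sign, 950 lost the call, 16 gained it, 53 moved and 9 reversed. The correlation of rad50Δ with mre11-H125N ran from 0.268 to 0.417 on leaving out wild-type libraries, that of mre11Δ from 0.196 to 0.293, and that of rad50Δ with mre11Δ from 0.877 to 0.891, and the first 2 were 0.486 and 0.354 with the replicate block. Of the gene calls, 365 of 2885 were lost on leaving out a library and 367 of 6233 under other alternatives, and 47 of 77 named genes in rad50Δ, 50 of 80 in mre11Δ and 33 of 75 in rrp6Δ lost their call at least once. All 11 counts of coding genes stayed within 1.5 times under both pseudocounts, both filters, coding median ratios and transcript rows, and all 10 with edgeR. The estimated correlation ended 97 of 98 list calls. The cause was not tested for any change below unless stated.

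Over all groups the replicate numbers did not pair the samples: of 21 correlations of same-numbered deviations (-0.551 to 0.720), 5 were over 0.1, among them all 3 between wild type, rad50Δ and mre11Δ (0.720, 0.659 and 0.693). With a replicate block, 979 coding genes changed in mre11-H125N (81 without), 1570 in rrp6Δ (995) and 387 in ku70Δ (44), and the mre11Δ medians of XUTs and SUTs, 0.18 and 0.16, passed (adjusted p = 0.0135 for both). These mutants share numbers only with wild type 1 and 2, so by construction the blocked comparison rests on those libraries, and the added fit with wild type 1 and 2 only gave 962, 1500 and 379 with medians of 0.18 and 0.17 (adjusted p = 0.0114 for both). The added block over 6 libraries of these 3 groups gave 63 coding genes between rad50Δ and mre11Δ (9 without) and mre11Δ medians of 0.22 and 0.17 (adjusted p = 0.0108 and 0.0122). The same 6 without the block (added) gave 4 genes there, 263 in rad50Δ, 284 in mre11Δ and 547 in the average (2014, 1879 and 2338 with the block), with the same 2 medians called (0.22 and 0.17, adjusted p = 0.00529 and 0.00612), so the choice of libraries alone brought these 2 calls. None of these 4 fits called them with an estimated correlation (adjusted p = 0.132 to 0.352 for XUTs and 0.132 to 0.403 for SUTs). Against all libraries without a block, the block changed no other count by over 1.5 times.

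With only the groups compared, which leaves fewer libraries to estimate the spread, counts were 456 in rad50Δ (1391), 328 in mre11Δ (1342), 4 in mre11-H125N, 1266 in the average (1943), 327 between mre11Δ and mre11-H125N (914), 1 between rad50Δ and mre11Δ, and 524 in rrp6Δ. With a minimum of 1 log2, by construction fewer passed: 336, 364, 24, 363 and 390 in the first 5 of these, 211 in rrp6Δ, 1781 in xrn1Δ (3792), 859 in MMS (2622) and 399 in the average minus mre11-H125N (1269). DESeq2 called 684 in mre11-H125N and 54 between rad50Δ and mre11Δ, where edgeR called 94 and 8. TMM factors moved the rrp6Δ count to 2045 (174 higher and 1871 lower, against 482 and 513) and the rad50Δ split to 523 and 1108 (against 714 and 677), and the median of all coding genes to -0.29 and -0.11. The added fit with wild type 3 and 4 only gave 122 in mre11-H125N. Without the number 1 libraries (added), 925 changed in rad50Δ, 821 in mre11Δ and 3 between them. With no filter the difference between top and bottom bins of level in xrn1Δ was -2.11 (-2.31), and with a mean of 50 the CUT median in xrn1Δ was -0.43 (adjusted p = 0.0402).

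Leaving out single libraries, where a lone sample is assumed to vary like the other groups, gave these ranges of counts: rad50Δ 290 to 1486, mre11Δ 596 to 1513, mre11-H125N 6 to 284, the average 1417 to 1998, mre11Δ against mre11-H125N 162 to 977, rad50Δ against mre11Δ 4 to 110, rrp6Δ 343 to 1152, xrn1Δ 3073 to 3839, ku70Δ 33 to 127, MMS 1624 to 2824, and the average minus mre11-H125N 238 to 1369. The rad50Δ medians ran from 0.30 to 0.42 for XUTs, 0.23 to 0.37 for CUTs and 0.26 to 0.40 for SUTs.

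Reversals were few and none had passed after the reversal. The SUT median of mre11-H125N went from 0.03 to -0.00114 and -3.88e-04 without wild type 1 or 2, within a range up to 0.0473, and its CUT median from -0.03 to 0.0491 without wild type 4, within a range down to -0.0553. The pheromone median of mre11Δ went from -0.82 to 0.15 without its first library, which has the lower pheromone genes of the 2, and to -1.63 without the other. With wild type 3 and 4 only (added), the XUT and SUT medians of mre11-H125N were -0.00776 and -0.0490, the SUT median of ku70Δ was -0.00912, and the iron medians were 0.10 in mre11-H125N (-0.35) and 0.22 in ku70Δ (-0.41). Thinned to the 7512010 reads over ORF rows of the shallowest library (mre11Δ), 1720 of 1943 coding calls in the average were kept.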

Other observations

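The genes of this part, the tests of mitochondrial rows and that of the choice of wild type were chosen after the values were seen, and the tests of overlap, low counts and level before their results were. Leucine genes set some strains apart: LEU2, a target of the regulator Leu3, stood at 2774 ± 269 in wild type, 5338 ± 432 in rad50Δ (log2 change 0.95, adjusted p = 0.00100), 411 and 553 in rrp6Δ (log2 change -2.53, adjusted p = 1.44e-07) and 519 in ku70Δ (log2 change -2.41, adjusted p = 1.58e-05, assumed to vary like the other groups). LEU4, of the same pathway, moved little in rrp6Δ (log2 change -0.38, adjusted p = 0.0103) and ku70Δ (log2 change -0.01, adjusted p = 0.978), and LEU3 itself did not change in rrp6Δ (log2 change 0.19, adjusted p = 0.201). In xrn1Δ, LEU2 (log2 change -0.86, adjusted p = 1.87e-04), LEU1 (log2 change -2.26, adjusted p = 5.09e-08), BAT1 (log2 change -2.26, adjusted p = 3.56e-08), OAC1 (log2 change -1.45, adjusted p = 8.49e-07) and LEU4 (log2 change -0.93, adjusted p = 2.52e-06) fell as well, and LEU3 rose (log2 change 0.70, adjusted p = 7.42e-05).

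Marker loci differed as well. URA3 had a mean of 7676 in wild type, 4189 in rad50Δ, 1309 in mre11Δ, 2213 in mre11-H125N, 1960.0 in rrp6Δ, 3234 in xrn1Δ, 1826 in ku70Δ and 2933 in MMS. The divergent row beside it on chromosome 5 (divergent_1068, 116711 to 117173) stood at 3035 in wild type, 6257 in rad50Δ, 4291 in xrn1Δ and 4958 in MMS. It stood at 3.26 in mre11Δ, 22.1 in mre11-H125N and 14.9 in ku70Δ, with 541 in rrp6Δ (log2 change -2.48, adjusted p = 2.25e-06). XUT0391 beside TDH3 (chromosome 7, 884006 to 884209), whose promoter the cassette named in the labels uses, stood at 239 in wild type and 3.06, 3.51 and 2.99 in mre11Δ, mre11-H125N and ku70Δ, with 53.7 in rrp6Δ (log2 change -2.12, adjusted p = 0.0120). It stood at 399 in rad50Δ, 144 in xrn1Δ and 286 in MMS. Both rows were near absent only in mre11Δ, mre11-H125N and ku70Δ. These strains thus differed from wild type there as well as in the named mutation. ADE2, the marker of xrn1Δ, stood at 2619.7 and 2808 there. The signal recognition particle RNA SCR1 (chromosome 5) ran from a normalized count of 1125774 to 1490402 in wild type, and stood at 45120.3 and 690462 in the mre11-H125N libraries, 129751 and 776541 in rrp6Δ, 97159 in ku70Δ and 28810.0 and 12764 in xrn1Δ.

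The near absence of mitochondrially encoded transcripts in xrn1Δ was weighed against 3 explanations. Loss of all mitochondrial DNA from the strain would leave no such row high unless its reads came from another locus, and 1 of 57 mitochondrial rows with reads, the dubious Q0092, stood above every other library (784 and 1126 reads in xrn1Δ), while the 19 rows with a wild-type mean of at least 1000 all lay at least 873-fold below it. Selection of RNA classes during library preparation would not single them out, and their median of -10.77 log2 lay far from the lowest snoRNA, at -4.50. Loss of a part of the DNA stays open, and so does loss of all of it, since how reads with several alignments were counted is not stated and Q0092 is a single row, and whether the absence of Xrn1 is the cause could not be told from 2 libraries of 1 strain. Lists added after this was seen gave 0 of 35 nuclear respiratory genes rose and 31 fell in xrn1Δ (median log2 -1.24), with 31 falling in MMS too (-1.47), and 5 of 15 retrograde and drug resistance genes rose and 3 fell in xrn1Δ. Those that rose were PDR3 (log2 1.85), PDR5 (1.83), PDR15 (1.87), RTG3 (1.26) and PDH1 (1.06). SNQ2 (-0.88), DLD3 (-1.23) and RTG2 (-0.44) fell. CIT2 (0.29), ATO3 (0.02), PYC1 (0.07), ACO1 (-0.08), IDH1 (-0.08), IDH2 (-0.05) and RTG1 (-0.36) did not pass the threshold. Among all 5580 coding genes 1961 rose and 1831 fell in xrn1Δ, so the share of this list that rose was near that of all genes. Whether the state of this strain contributed to the other xrn1Δ changes was not tested.

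The rise of XUTs, CUTs and SUTs in rad50Δ, weighed against 3 technical explanations, was not tested against a biological one, and each class call ended with an estimated correlation (adjusted p = 0.0639, 0.220 and 0.0639). Reads of overlapping genes on the same strand may not explain it, since the median was 0.34 log2 without such overlap. Nor may counts near the pseudocount (0.29 at a mean of at least 100) or the choice of wild type (0.26 in the smaller choice). Coding genes in the lowest bins of wild-type level had medians of 0.59, 0.21 and 0.05 log2 in rad50Δ, from the lowest bin upward. Level and change were taken there from different wild-type libraries. The classes were not compared with coding genes of like level, so a rise of weakly expressed RNA in general stays open. In xrn1Δ, the lower change of abundant coding genes was seen at up to 30.2% of its size in the deeper libraries of mre11-H125N, rrp6Δ or ku70Δ, and at up to 41.6%, 43.2% and 36.6% in rad50Δ, mre11Δ and MMS, so a part could come from normalization or saturation, and this test could not tell.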
